A study of Mus musculus and Homo sapiens with 21 samples.

How the data were processed

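RNA-seq of E12.5 mouse gut epithelium was analysed from the authors' deposited table of FPKM (fragments per kilobase of transcript per 1000000 mapped fragments), which holds 23951 genes and 4 libraries. Per the labels' protocols, gut tubes caudal of the stomach were treated with 0.25% trypsin for 7 to 10 minutes, Epcam-positive cells were enriched on magnetic beads, RNA was isolated in TRIzol and cleared of DNA, and libraries were made with a SMARTer Ultra Low Input kit. This kit primes on poly(A) tails and does not mark strand. Per the labels, the replicates are biological and the mice are of mixed background. The table is a Cuffnorm output, per the labels' description, and Cuffnorm scales libraries to each other. TopHat2 2.1.0, Bowtie2 2.2.6, deepTools 2.4.2, Cuffnorm and the builds mm9 and hg19 are named, per the submitters' processing notes, for the series as a whole and with no role. The gene annotation, the Cuffnorm version and its scaling option are not given in the sources used here. The ChIP-seq and ATAC-seq samples were not analysed here.

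Columns of the table were assigned to the wild type or the knockout group by their names. Their suffixes, 0 and 1, do not state which replicate number of the labels they stand for, so no replicate was paired across groups. No column was left without a group. FPKM keeps no read counts. Values below 0.3 FPKM were compared between libraries for a common step, and the commonest ratio, 1.35 between KO_0 and KO_1, held 9.7% of 2237 genes within 0.02 on the log2 scale, with 1.35% to 2.79% in the other pairs, so no reads could be recovered and the depth of each library is unknown. An exact 0 was treated as listed at 0, since genes that every cell uses were also listed at 0, and no fold change is given against a group at 0.

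Symbols were matched to a RefSeq gene table of assembly GRCm38.p6 by symbol or unique synonym. No match was found for 155 symbols. As the build differs from those named for the series, the table was used only for biotype, gene span and which genes overlap, and no coordinates are printed.

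Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A fold change on this scale understates the change of genes with low values. Values are given as mean ± SD of 2 libraries and log2 fold changes as knockout minus wild type. Lists of genes were written from general knowledge of the tissue before the data were examined, and 26 lists with at least 5 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation, camera on ranks and fry as alternatives. Members were also counted after adjustment over the list alone. Some lists share members, such as Vsig1 in the stomach and fetal lists.

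Genes are named by a rule written before the data were examined: Cdx2, then the 12 highest and 12 lowest log2 fold changes among called genes whose groups do not overlap and whose higher group has a mean of at least 5 FPKM, leaving out symbols of predicted genes, clones, miRNAs and snoRNAs by their prefixes, then up to 4 members of each list with the smallest p and each member called against its list's median, then markers of other cell types above 50 FPKM. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been looked up after their values were seen.

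Data were simulated with the wild type means, moderated variances shuffled across genes and independent normal noise, and 200 of 12877 genes were changed. The changed genes were drawn from those with a wild type mean log2(FPKM + 1) above 2, so recovery among lower genes was not measured. On the simulated data the test recovered 89% of changes of 1 and 100.0% of changes of 2 on the log2 scale for this comparison. Of its calls, 10.0% were false, above the nominal rate. Camera gave p under 0.05 for 1.5% of 200 unchanged lists. In the real data 5422 genes were called and estimated correlations within lists reached 0.82 (endothelial markers), so these rates need not hold there. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, rescaling each library to the same total, quantile normalization, median centring, eBayes without trend and with robust fitting, a test against a 1.5-fold change, and leaving out each library. Chosen after the data were seen were a test of protein-coding genes alone and the same with a lowess trend of each library on log10 gene span removed. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.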

Results

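The series holds 21 samples that address how CDX2, a homeodomain transcription factor of the intestinal epithelium, acts during intestinal development. The 4 RNA-seq libraries were analysed here. The 5 mouse and 6 human CDX2 ChIP-seq samples, the 4 ATAC-seq samples and the 2 ChIP inputs were not analysed here. The RNA-seq libraries came from mouse embryos at E12.5 (embryonic day), from gut caudal of the stomach that was dissociated with trypsin and enriched on magnetic beads for cells bearing Epcam, a surface protein of epithelial cells. The comparison asks which transcripts of the early intestinal epithelium depend on Cdx2. It sets 2 wild type libraries (floxed Cdx2 alleles without Cre) against 2 knockout libraries, in which Cre recombinase expressed from Shh, a gene active in the gut endoderm, deletes Cdx2. The wild type libraries are called WT_0 and WT_1 and the knockout libraries KO_0 and KO_1, after the suffixes in the table. The values are FPKM, so the number of reads behind them is unknown. FPKM summed to 588979 and 576734 in WT_0 and WT_1 and to 564109 and 529877 in KO_0 and KO_1, and 12911, 12605, 12472 and 12539 genes, in the same order, had at least 1 FPKM. The libraries of the groups differed in composition: miRNA and snoRNA genes held 14.2% and 13.9% of the summed FPKM in WT_0 and WT_1 and 23.6% and 22.3% in KO_0 and KO_1. Most of the knockout share came from 1 gene, Mir682, at 9548 and 12809 FPKM in wild type and 103458 and 91203 FPKM in knockout. Of the 78 miRNA genes tested 14 were higher and 29 lower in the knockout, and of the 42 snoRNA genes 6 were higher and 17 lower. The 10 highest genes of each library held 12.1% in both wild type libraries and 22.3% and 21.0% in the knockout libraries. Spearman's rho across genes was 0.963 between the wild type libraries, 0.977 between the knockout libraries and 0.950 to 0.955 across the groups. Genes are not independent replicates, so these coefficients only describe the libraries.

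Cdx2 itself stood at 125 and 160 FPKM in the wild type libraries and at 37.1 and 37.6 FPKM in the knockout libraries. The log2 fold change was -1.89 ± 0.14 (SE) with adjusted p = 0.00136 by limma, and both knockout libraries lay below both wild type libraries. The groups did not overlap in 9766 of 12877 genes tested (75.8%, against 33.3% by chance), so the lack of overlap does not set Cdx2 apart. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. The gene-level value does not tell exons inside the deleted part from those outside it, so it does not measure how much of the gene was deleted. The paralog Cdx1, looked up after its values were seen, stood at 2.96 ± 1.55 FPKM (SD, n = 2) in wild type and 0.709 ± 0.304 FPKM in knockout, a log2 fold change of -1.17 ± 0.30 (SE) with adjusted p = 0.0249. With the trend of fold changes on gene span described below removed, Cdx1 had a log2 fold change of -0.95 ± 0.31 and an adjusted p of 0.0596.

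**Figure D1:**
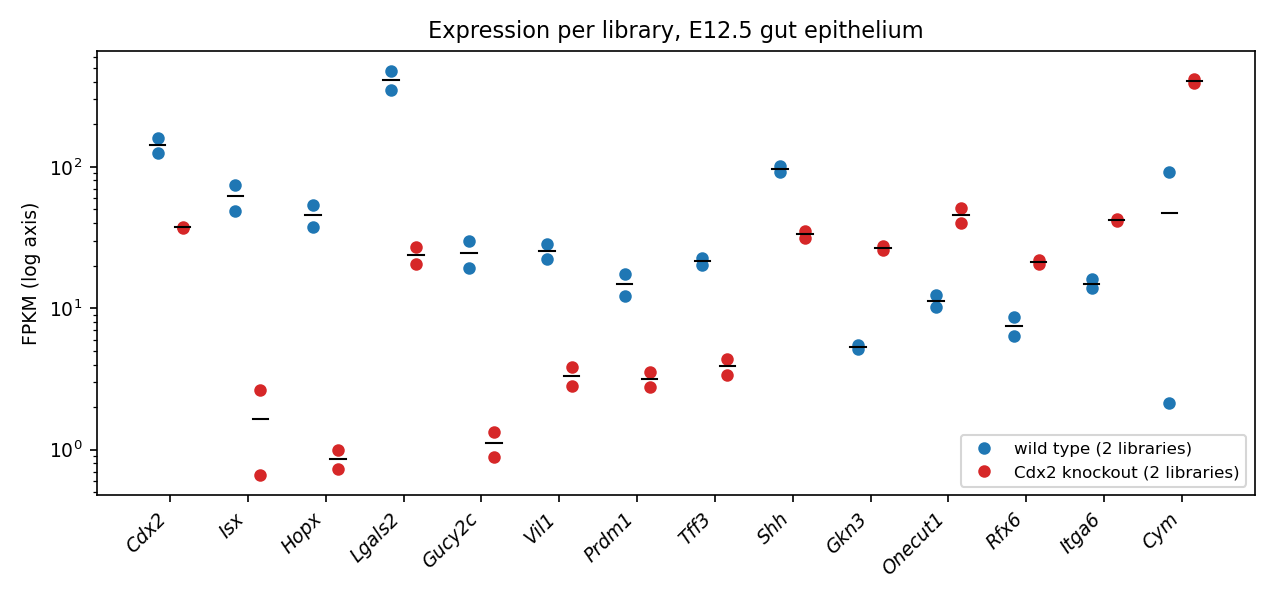
FPKM on a log axis for 14 of the genes named in the text, with wild type libraries in blue, knockout libraries in red (2 points each) and the group mean as a black bar. Cdx2 lies at 125 and 160 FPKM in wild type and 37.1 and 37.6 FPKM in knockout, and the wild type values of Cym, 92.5 and 2.14 FPKM, are the farthest apart of those drawn.

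Among the genes taken by the rule for the lowest fold changes in the knockout were Isx, Hopx, Osr2, Lgals2, Folr1, Gucy2c, Cib2 and Lypd8. Isx, a homeobox gene of the intestine that represses vitamin A absorption genes, stood at 61.8 ± 18.1 FPKM (SD, n = 2) in wild type and 1.65 ± 1.40 FPKM in knockout, a log2 fold change of -4.64 ± 0.39 (SE, adjusted p = 0.00193). Lgals2, which encodes a galectin, went from 413 ± 89.7 to 23.7 ± 4.64 FPKM. Hopx, a homeodomain-only protein gene, fell by 4.63 on the log2 scale, the zinc finger gene Osr2 by 4.18, the folate receptor gene Folr1 by 3.60, Gucy2c, the receptor for guanylin, by 3.58, the calcium-binding protein gene Cib2 by 3.16 and Lypd8 by 3.03. The adjusted p of these 6 genes ran from 0.000135 for Hopx to 0.00162 for Lypd8. In the opposite direction, Itih2, a heavy chain gene of the inter-alpha-trypsin inhibitor, rose from 1.75 ± 1.12 to 21.7 ± 3.70 FPKM (log2 fold change 3.10 ± 0.30, adjusted p = 0.00297). Cym, which encodes the milk-clotting protease chymosin of the newborn stomach, stood at 92.5 and 2.14 FPKM in the wild type libraries and at 418 and 394 FPKM in the knockout libraries. Its adjusted p was 0.0434, and the call was lost without KO_0, without KO_1 and in 5 further settings.

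Among the remaining genes with the most extreme changes, most share sequence with near-identical copies or overlap other transcripts, and their values are uncertain. Hba-a1 and Hba-a2, neighbouring alpha-globin genes of almost the same sequence, moved apart: Hba-a1 stood at 43.6 and 11.1 FPKM in wild type and 0.207 and 0.124 FPKM in knockout, while Hba-a2 stood at 0.0448 and 0.0140 FPKM in wild type and 27.7 and 22.0 FPKM in knockout. Ribosomal protein genes, a set looked up after its values were seen and one with many processed pseudogenes, moved both ways. Rps25 and Rpl19 had log2 fold changes of 4.75 and 3.70, and Rps28 stood at 0 and 1.23 FPKM in wild type and 20.3 and 19.6 FPKM in knockout. Across 57 ribosomal protein genes, 28 were higher and 12 lower, from -1.20 to 4.75 on the log2 scale. The SD of their log2 fold changes was 1.32, against at most 1.15 in 1000 random lists matched on mean expression, and the SD of their differences was 0.37 between the wild type and 0.20 between the knockout libraries. The pseudogenes Atp6v0c-ps2 (-3.33) and Pisd-ps1 (2.81), the galectin copy Lgals6 (-3.27), Usmg5 (3.13) and the snoRNA host gene Snhg9 (3.06) carry the same doubt. Both pseudogenes were near 0 FPKM in 1 group, so their fold changes hang on the pseudocount. They ran from -6.52 to -1.49 and from 1.15 to 5.71 over the alternative settings. Peg3os (4.55, and 2.46 to 7.82 over those settings), also near 0 FPKM in wild type, lies antisense to Peg3. Peg3 was looked up after its values were seen and rose from 113 ± 10.3 to 336 ± 58.5 FPKM (SD, n = 2, log2 fold change 1.55 ± 0.16 SE, adjusted p = 0.00342). The strand used in counting is not given in the sources used here, so reads of these 2 genes cannot be told apart. The snoRNA gene AF357425 was listed at 0 in both knockout libraries and at 108 and 186 FPKM in the wild type libraries.

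Of 12877 genes tested with limma, 5422 passed an adjusted p of 0.05, of which 1859 were higher and 3563 lower in the knockout, and 6777 had an unadjusted p under 0.05. Of the genes called, 419 were higher and 506 lower by at least 1 on the log2 scale. The count was 1112 without KO_0 and 349 without KO_1, where the spread comes from the wild type pair alone, and 5355 without WT_0 and 6626 without WT_1, where it comes from the knockout pair. The median log2 fold change of all genes was -0.14 without KO_0 and -0.15 without KO_1. Of 139 called genes taken by the naming rule besides Cdx2, 72 lost their call without KO_0, 92 without KO_1, 11 without WT_0 and 9 without WT_1. The 47 that kept it on leaving out each library in turn include, beside multi-copy, pseudogene and snoRNA genes, Isx, Hopx, Osr2, Lgals2, Lgals4, Folr1, Gucy2c, Cib2, Lypd8, Vil1, Espn, Prdm1, Tff3, Shh, Bmp4, Bmpr1a, Itih2, Gkn3, Onecut1, Itga6, Olfm4, Trp53inp1, Trf, Fgb, Igf2, Irf1, Ndrg1, Phlda3, Cldn3, Cldn7, Krt19 and Foxl1. With no filter on low values 3570 genes passed, and 264 passed a test against a 1.5-fold change. Higher genes made up 34.3% of the calls as deposited, 50.7% after quantile normalization and 42.7% after rescaling each library to the same total. The median log2 fold change of all genes was -0.15 as deposited and -0.02 after quantile normalization. Small changes are thus to be read relative to this shift.

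Fold changes also followed gene span, the length of a gene on the genome with its introns. Across 9339 protein-coding genes with a mean above 5 FPKM, Spearman's rho between the log2 fold change and the span was 0.37. The shortest eighth of these genes had a median log2 fold change of -0.48 and the longest eighth 0.14. The same rho was -0.01 between the wild type libraries and -0.34 between the knockout libraries, where the medians of the shortest and longest eighths were 0.12 and -0.07. After this trend was removed from protein-coding genes, 4151 genes passed, 2067 higher and 2084 lower, of which 3367 were also called in the same direction in the values as deposited. The removal also moved the median log2 fold change of the 12281 protein-coding genes tested from -0.15 to -0.02, so a small negative call that ended was not traced to the span itself. Counts after removal are given below beside each list whose counts they alter, and the removal was chosen after the data were seen.

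**Figure D2:**
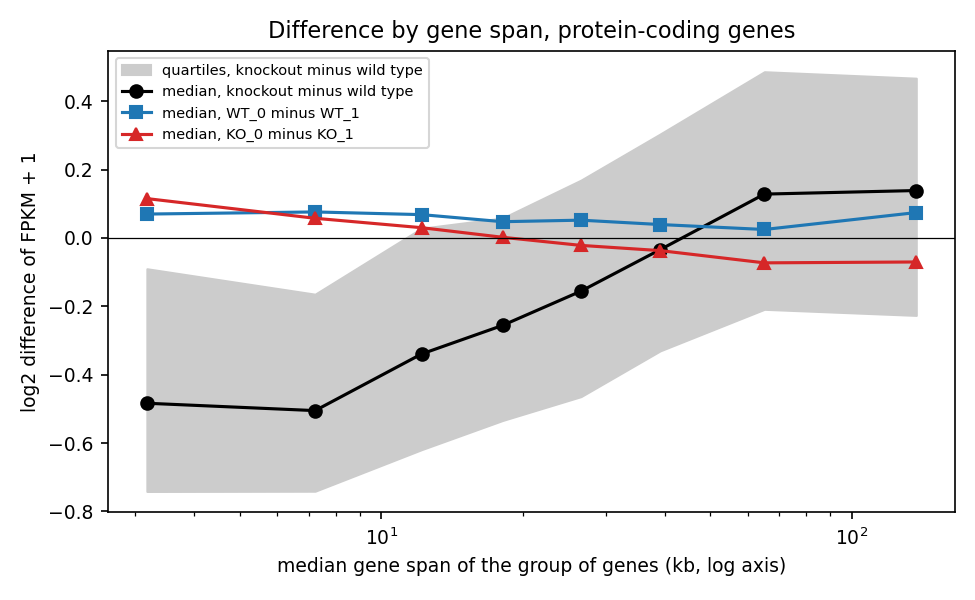
Median log2 difference of FPKM + 1 (vertical axis) for 8 groups of protein-coding genes ordered by gene span (horizontal axis, kb, log scale). Black is knockout minus wild type with quartiles in grey, blue is WT_0 minus WT_1 and red is KO_0 minus KO_1. The black line runs from -0.48 in the shortest genes to 0.14 in the longest.

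The list of enterocyte and brush border genes fell as a group in the knockout. Of 29 tested members 22 were lower, 1 was higher and 6 did not pass (23 lower and 1 higher when adjusted over the list alone), and the median log2 fold change was -1.07. Lgals2, the galectin gene Lgals4 (42.1 ± 9.28 to 5.73 ± 0.41 FPKM, SD, n = 2), the microvillus gene for villin, Vil1 (25.3 ± 4.44 to 3.33 ± 0.74 FPKM), and the actin-bundling gene Espn (34.9 ± 0.46 to 11.2 ± 1.09 FPKM) had the smallest p. The member called against the rest was Slc2a2, a glucose transporter gene, at 2.22 ± 0.33 and 5.81 ± 2.32 FPKM, and that call was lost without WT_0 and without KO_1. The camera test of limma gave an adjusted p of 1.99e-05 over 26 lists, and with the gene span trend removed 20 members were lower and 1 higher, the median was -0.96 and the adjusted p 3.23e-07. The list did not pass with an estimated correlation (adjusted p = 0.959), nor did any other list, and fry, which tests whether a list's genes move on balance one way and compares them with no other genes, gave an adjusted p of 0.0628.

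Of the intestinal transcription factors, 9 of 21 tested members were lower and none was higher, the same when adjusted over the list alone. Isx, the repressor gene Prdm1 (14.8 ± 3.57 to 3.15 ± 0.55 FPKM, SD, n = 2) and the zinc finger gene Gata6 (32.7 ± 2.13 to 16.3 ± 0.32 FPKM) were among those lower. Hnf4a, which encodes a nuclear receptor of the intestinal and liver epithelium and was looked up after its values were seen, stood at 24.7 ± 0.57 and 21.8 ± 2.21 FPKM and did not pass (adjusted p = 0.283). The list's median was -0.57 and it did not pass as a group (adjusted p = 0.101), but it passed without KO_1 (adjusted p = 0.0144) and with the gene span trend removed (adjusted p = 0.0203, median -0.30, 7 members lower and 1 higher).

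The stomach list did not pass as a group (median 0.16, adjusted p = 0.279), with 3 of 17 members higher and 1 lower (2 higher and 1 lower when adjusted over the list alone, 4 and 1 with the gene span trend removed). It passed without WT_0 (median 0.56, adjusted p = 0.000439) and had a median of -0.11 without WT_1 (adjusted p = 0.632). The gastrokine gene Gkn3 rose from 5.29 ± 0.25 to 26.6 ± 1.36 FPKM (SD, n = 2; log2 fold change 2.13 ± 0.13 SE, adjusted p = 0.000533). Vsig1, a junction protein gene of the stomach, stood at 3.59 and 1.14 FPKM in wild type and 8.19 and 8.23 FPKM in knockout, and Irx2 at 5.43 and 2.32 against 7.80 and 8.16 FPKM; both calls were lost without either knockout library. Pllp was lower (-1.34). Sox2, a transcription factor gene of foregut epithelium looked up after its values were seen, stood at 36.0 and 2.00 FPKM in the wild type libraries and 41.9 and 35.0 FPKM in the knockout libraries, and did not pass (adjusted p = 0.187). Of the esophageal list 1 of 11 members was higher and 1 lower, the same over the list alone (median -0.11, adjusted p = 0.847). These were Itga6, which encodes an integrin of the basal cell surface (14.9 ± 1.56 to 42.1 ± 1.20 FPKM), and Klf7 (-0.72), while Trim29 (-0.71) and Krt17 (-0.84) did not pass. Of 6 lung and thyroid genes Lamp3 alone was called, at 0.506 and 1.99 FPKM on average, in both counts (median -0.10, adjusted p = 0.769).

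Genes of the pancreas and liver moved both ways, with 4 of 21 higher and 3 lower (2 and 3 adjusted over the list alone, median -0.30, adjusted p = 0.775). With the gene span trend removed the list's median was 0.04 (adjusted p = 0.960). The liver and pancreas transcription factor gene Onecut1 rose from 11.3 ± 1.54 to 45.7 ± 7.67 FPKM (SD, n = 2; adjusted p = 0.00216). Alb (1.44), Pdx1 (0.69) and Hhex (0.57) were higher as log2 fold changes, and the transferrin gene Trf (-1.66) and the fibrinogen gene Fgb (-2.29) were lower. The calls of Pdx1 and Hhex were lost without either knockout library. Goblet and enteroendocrine genes had 1 of 19 members higher and 3 lower (1 and 1 adjusted over the list alone, median -0.38, adjusted p = 0.769), and 2 higher and 2 lower with the gene span trend removed, when the median turned to 0.04. Tff3, a trefoil peptide gene of goblet cells, fell from 21.4 ± 1.87 to 3.88 ± 0.69 FPKM, and Rfx6, a transcription factor gene of endocrine progenitors, rose from 7.47 ± 1.60 to 21.3 ± 0.94 FPKM. Agr2 stood at 23.7 and 4.98 FPKM in wild type and 1.52 ± 0.03 FPKM (SD, n = 2) in knockout, and Fev was lower (-0.62), but not called with the gene span trend removed (-0.20).

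**Figure D3:**
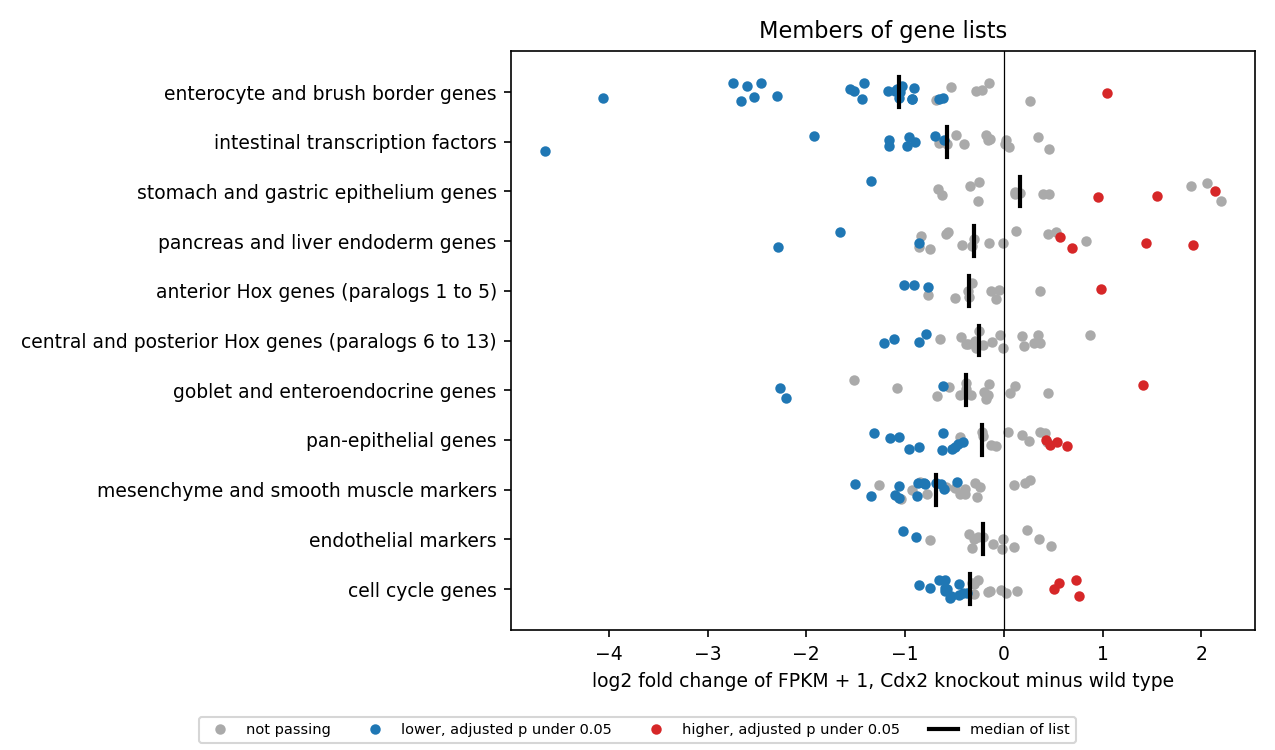
Log2 fold change of FPKM + 1, knockout minus wild type (horizontal axis), for the tested members of 11 of the 26 lists, with the list median as a black bar, called members in blue (lower) or red (higher) and others in grey. The enterocyte list has its median at -1.07 and the mesenchyme list at -0.69, and these are the lists that passed.

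Hox genes, which mark position along the body axis, did not pass as groups. The anterior list had 1 of 13 members higher and 3 lower (1 and 2 adjusted over the list alone, median -0.36, adjusted p = 0.705), and the central and posterior list 4 of 21 lower (3 over the list alone, median -0.25, adjusted p = 0.769). Hoxc6 (-0.86) and Hoxb6 (-1.21) were lower, as were Hoxb2 (-0.77), Hoxd4 (-1.01), Hoxb5 (-0.90), Hoxb8 (-1.12) and Hoxc8 (-0.79), but the calls of these last 5 ended when the gene span trend was removed, with log2 fold changes from -0.70 for Hoxb8 to -0.36 for Hoxb2. The anterior list then had 1 member higher and none lower, and the central and posterior list 2 lower, and the median of the latter turned from -0.25 to 0.17.

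In the signalling list, 7 of 32 genes were higher and 6 lower, the same over the list alone (median -0.03, adjusted p = 0.705). The ligand gene Shh fell from 96.7 ± 6.60 to 33.5 ± 2.63 FPKM (SD, n = 2; log2 fold change -1.50 ± 0.12 SE, adjusted p = 0.00154). The Shh locus also carries the Cre in the knockout, and the wild type embryos carry no Cre. An effect of the Cre allele on Shh or on other genes thus cannot be told apart from the loss of Cdx2. Bmp4 (-1.12) was lower, and the receptor genes Bmpr1a (1.29), Notch2 (1.26), Notch1 (1.02) and Ptch1 (0.76), the Notch ligand gene Jag1 (0.91), Spry2 (0.56) and Fgfr2 (0.40) were higher. With the gene span trend removed 10 members were higher and 5 lower, the median turned to 0.25, and Fgfr2 (0.24) was no longer called. Of the Wnt target and stem cell list 3 of 22 were higher and 7 lower (6 and 8 over the list alone, median -0.03, adjusted p = 0.705), and 3 higher and 4 lower with the trend removed, when the median turned to 0.02. Olfm4, Prom1 and Lgr4 were the higher members, at 1.42, 0.56 and 0.42, and Ascl2 (-1.18), Tcf7 (-0.80) and Myc (-0.75) had the smallest p among the lower members. The calls of Lgr4 (0.26) and Myc (-0.32) ended with the trend removed. Fetal epithelial genes had 3 of 17 members higher and 9 lower, the same over the list alone (median -0.46, adjusted p = 0.705). With the trend removed 3 were higher and 6 lower (median -0.20, adjusted p = 0.960). Igf2 fell from 622 ± 28.1 to 312 ± 55.4 FPKM, Dlk1 (-1.06) and Ccnd2 (-0.98) were lower, and Lin28b (0.93), Gja1 (0.50) and Vsig1 were higher.

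Lists of general cell function did not pass as groups by camera. Cell cycle genes had 4 of 26 higher and 13 lower (4 and 14 over the list alone, median -0.34, adjusted p = 0.362), but 4 higher and 3 lower with the trend removed. Ccnb1 (0.76), Top2a (0.73), Bub1 (0.56) and Mki67 (0.51) were higher, and Aurka (-0.75) and Ccnb2 (-0.65) lower. Of the glycolysis and hypoxia list 2 of 19 were higher (Pgam1 and Pdk1, 0.59 and 0.40) and 9 lower, the same over the list alone, with Ndrg1 (-1.44), Aldoa (-0.86), Slc2a1 (-0.75) and Pfkl (-0.67) first (median -0.31, adjusted p = 0.705), and 3 higher and 7 lower with the trend removed. By fry it passed as lower (adjusted p = 0.0156). Lipid and cholesterol genes had 4 of 28 higher and 8 lower (4 and 9 over the list alone, median -0.18, adjusted p = 0.857), but 4 higher and 3 lower with the trend removed. The lipid synthesis genes Fasn (0.89), Acaca (0.72), Acly (0.46) and Scd2 (0.45) were the higher members, and Plin2 (-0.64) and Dgat1 (-0.60) were lower. The calls of Acly (0.39) and Dgat1 (-0.26) ended with the trend removed. Apoptosis and p53 target genes had 2 of 18 higher and 8 lower (4 and 8 over the list alone, median -0.27, adjusted p = 0.705), and 4 higher and 7 lower with the trend removed. Trp53inp1 rose from 3.18 ± 0.58 to 15.4 ± 2.54 FPKM (SD, n = 2), Bcl2l11 was higher (0.81), and Pmaip1 (-1.41), Phlda3 (-1.30) and Bax (-0.88) were lower. Immediate early and heat shock genes, which respond to dissociation, had 9 of 17 lower and 1 higher, the same over the list alone (median -0.50, adjusted p = 0.279), and 2 lower and 1 higher with the trend removed. The list passed without KO_1 (median -0.57, adjusted p = 0.0398). Jund (-1.06) and Atf3 (-0.79) were lower and Hspa8 (0.49) higher, and the calls of Dusp1 (-0.70) and Ier3 (-0.79) ended with the trend removed, at -0.28 and -0.49. MHC and interferon genes had 4 of 16 lower (3 over the list alone, median -0.18, adjusted p = 0.705), led by Irf1 (26.5 ± 0.63 to 6.35 ± 0.80 FPKM), then Ifit1 (-1.04), H2-K1 (-0.72) and H2-T23 (-0.62). With the trend removed 4 members were higher and 2 lower (median 0.07), and H2-K1 (-0.30) and H2-T23 (-0.21) were no longer called. Replication-dependent histone genes, most of which lack a poly(A) tail, had 7 of 16 higher and 2 lower, the same over the list alone (median 0.35, adjusted p = 0.106). The list passed with the trend removed (9 higher and 2 lower, median 0.61, adjusted p = 0.0296) and without KO_1 (median 0.43, adjusted p = 0.0144). Hist1h3c (0.97) and Hist1h2ac (1.27) were higher, and Hist1h1d (-1.01) and Hist1h1a (-0.87) lower.

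Markers of cells other than epithelium were present in all 4 libraries. Mesenchyme and smooth muscle markers were lower as a group in the knockout, beside the fall of the enterocyte genes, with 13 of 29 lower and none higher, the same over the list alone (median -0.69, adjusted p = 0.0162). That call was lost without WT_0 (median -0.45) and with an estimated correlation (adjusted p = 0.959). With the gene span trend removed 6 members were lower and 1 higher, and the median was -0.41 (adjusted p = 0.0201). Tcf21 stood at 298 ± 65.6 and 137 ± 9.85 FPKM (SD, n = 2), Foxf1 at 268 ± 30.8 and 171 ± 1.37, Vim at 170 ± 3.89 and 92.7 ± 1.97, Foxf2 at 84.2 ± 2.06 and 45.2 ± 0.81, Acta2 at 557 ± 205 and 221 ± 92.2, and Nkx2-3 at 97.4 ± 16.0 and 59.8 ± 2.25, all lower. The calls of Foxf1, Acta2 and Nkx2-3 ended with the gene span trend removed. Foxf1 went from -0.64 ± 0.13 (SE) to -0.21 ± 0.11 and Nkx2-3 from -0.69 ± 0.14 to -0.26 ± 0.16 on the log2 scale, whereas Acta2 kept most of its fold change, -1.34 ± 0.35 and then -1.10 ± 0.34, at an adjusted p of 0.0506. Foxl1 was also lower (-1.50). Abundant members that did not pass were Col3a1 at 384 ± 124 and 306 ± 19.9 FPKM, Actg2 at 220 ± 77.2 and 125 ± 58.3, Col1a1 at 206 ± 108 and 137 ± 13.2, Col1a2 at 110 ± 66.4 and 57.7 ± 2.50, Postn at 57.3 ± 35.3 and 24.7 ± 0.30, and Col6a1 at 51.3 ± 13.7 and 38.1 ± 1.06.

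Pan-epithelial genes had 4 of 26 higher and 11 lower (5 and 12 over the list alone, median -0.22, adjusted p = 0.769), but 7 higher and 6 lower with the gene span trend removed (median -0.11). This list passed by fry as lower (adjusted p = 0.0114). Epcam, the marker the cells were enriched by and looked up after its values were seen, was lower, at 471 ± 44.4 and 334 ± 13.2 FPKM (SD, n = 2; log2 fold change -0.49 ± 0.13 SE, adjusted p = 0.0265), and did not pass with the trend removed (-0.25 ± 0.13, adjusted p = 0.195). Cldn7 (-1.31), Krt19 (-1.15), Cldn3 (-0.96) and Rab25 (-0.86) were lower, and Grhl2 (0.64), Foxa1 (0.54), Esrp1 (0.47) and Cdh1 (0.42) were higher, of which Cdh1 was not called with the trend removed (0.30). Endothelial markers had 2 of 15 lower and none over the list alone (median -0.21, adjusted p = 0.857), namely Egfl7 (-0.89) and Sox18 (-1.02), while Ramp2 (0.36) and Plvap (-0.74) did not pass. With the trend removed Egfl7 (-0.58) and Sox18 (-0.64) were not called and Ramp2 was higher (0.74), the 1 member called. Immune markers had 5 of 13 lower, the same over the list alone (median -0.44, adjusted p = 0.292), first C1qb (-1.03), Coro1a (-0.92), Laptm5 (-0.61) and C1qa (-0.67), and 2 lower and 1 higher with the trend removed, when Coro1a (-0.50) and C1qa (-0.25) were not called. Neural crest and enteric neuron markers had 1 of 15 higher and 3 lower (1 and 2 over the list alone, median -0.29, adjusted p = 0.775), with Erbb3 higher (0.58) and Elavl4 (-0.71), Hand2 (-0.97) and Stmn2 (-0.85) lower. With the trend removed 1 was higher and 2 lower, and Hand2 (-0.55) was not called. Of 9 erythroid markers only Hba-a1 and Hba-a2 were called, in both counts (median -0.23, adjusted p = 0.933). With the trend removed the list's median was 0.19 (adjusted p = 0.960). Hbb-y stood at 212 ± 102 and 150 ± 18.2 FPKM (SD, n = 2), Hba-x at 49.0 ± 27.8 and 23.1 ± 1.42 and Klf1 at 1.66 and 1.26 on average. Of 6 embryo sex genes Xist (1.74) and its overlapping antisense gene Tsix (1.35) were higher in both counts. As the kit does not mark strand, reads from their overlap cannot be told apart. Xist stood at 0.672 and 3.70 FPKM in wild type and 6.07 and 11.4 FPKM in knockout, and both calls were lost without WT_0 and without KO_1. Uty (0.34) and Kdm5d (0.11) did not pass (list median 0.22, adjusted p = 0.292). This list passed without KO_1 (median 0.59, adjusted p = 0.0144), and of its 4 protein-coding members none was called with the trend removed. In 6 lists the median was negative although camera, which compares a list with all other genes, put it above them. These were the esophagus, lung and thyroid, pancreas and liver, Wnt, signalling and erythroid lists, and the mean of the lung and thyroid list was positive.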

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

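No paired analysis was possible because the table's columns carry no label replicate number. Cdx2 stayed lower and past the threshold in each of the 16 other settings, from -2.07 to -1.48 on the log2 scale. The count of 5422 changed genes became 3570 (1120 higher) with no filter, 264 (105 higher, 159 lower) against a 1.5-fold change, and 349 to 6626 on leaving out a library (125 to 2293 higher, 224 to 4333 lower). In the 3-library fits the lone sample of a group is assumed to vary like the other group. Leaving out a knockout library leaves the spread to be set by the wild type pair, which differed more. The lower count of 3563 was 2373 after quantile normalization and 2084 with the gene span trend removed from protein-coding genes, an alternative chosen after the data were seen; the cause was not tested. The enterocyte list kept its direction in each setting, with medians from -1.63 (pseudocount 0.1) to -0.55 (pseudocount 5), and passed except with an estimated correlation (median -1.07, adjusted p = 0.959) and by fry (-1.07, 0.0628). The mesenchyme list (median -0.69) did not pass with an estimated correlation, by fry (adjusted p = 0.145) or without WT_0, and its median ran from -0.89 to -0.45 on leaving out a library. An estimated correlation has only the residual degrees of freedom of 4 libraries. The number of lists called, 2, became 0 with an estimated correlation, 4 with the gene span trend removed and 2 to 6 on leaving out a library. Fry, a test of another question, called the glycolysis and the pan-epithelial lists. Neither of the 2 called lists turned its direction. Of the 5422 called genes, only Mir686 was called in the opposite direction in any setting (-0.85 and, after quantile normalization, 0.29), and with the gene span trend removed 43 of 5201 had the opposite sign without being called. Of the comparisons of named genes other than Cdx2 with an alternative, 173 lost and 5 gained a call in planned settings, 184 and 12 on leaving out a library, and 24 and 3 in the added settings. Depth is unknown, so the precision of low values cannot be stated.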

Other observations

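The tests in this part were chosen after the results they concern were seen, as were the genes named here. The following genes lie outside the lists and were picked because their values differed, so they test no group. Among genes lower in the knockout, Clrn3 stood at 7.81 ± 2.31 and 0.226 ± 0.048 FPKM (SD, n = 2), the bile acid and steroid transporter gene Slc51a at 27.4 ± 9.29 and 3.13 ± 0.32, the microvillus scaffold gene Ush1c at 22.1 ± 4.74 and 2.82 ± 0.06, the mucin gene Muc13 at 5.25 ± 1.72 and 0.0556 ± 0.0297, and Pth1r, the parathyroid hormone receptor gene, at 166 ± 29.5 and 24.8 ± 3.95. Their adjusted p by limma ran from 0.000663 for Pth1r to 0.00233 for Muc13. Among genes higher in the knockout, the nuclear receptor gene Esrrg stood at 1.07 ± 0.31 and 11.2 ± 0.23 FPKM (adjusted p = 0.000765) and the glucose transporter gene Slc2a3 at 50.2 ± 6.08 and 215 ± 27.5 FPKM (adjusted p = 0.00093).

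Of 3 technical explanations weighed for the fall of the enterocyte list, gene span is argued against as the whole cause. After its trend was removed 20 of 29 members were lower, and the list's median was -0.96 with 95% bounds of -1.49 and -0.63. Bounds in this part are taken from the ranked fold changes of a list's genes, as if genes were independent. They leave out variation between libraries, so they describe only the spread across genes. The estimated correlation within the enterocyte list was 0.18. Dilution by other cell types would lower epithelial genes and raise markers of those cells. Epcam was lower (-0.49, and -0.25 and not called with the trend removed). The keratin genes Krt8 (0.37) and Krt18 (0.25) did not pass, and both were called higher with the trend removed (0.76 and 0.68). The pan-epithelial list (median -0.22) was lower by fry but did not pass by camera, and with the trend removed 7 members were higher and 6 lower. The median of 72 markers of mesenchyme, endothelium, immune cells and neural crest was -0.44 (bounds -0.60 and -0.29), and -0.18 with the trend removed. Of these, 29 were mesenchyme markers, and the endothelial, immune and neural crest lists had medians of -0.21, -0.44 and -0.29. These values speak against dilution only if the markers kept their level per cell, which was not tested. More stomach and less intestine in the knockout dissections would raise stomach genes. Gkn3, Vsig1 and Irx2 were higher, but 13 of the 17 members of the stomach list did not pass and Pllp was lower (-1.34). Cym, a stomach gene outside the list, stood at 92.5 and 2.14 FPKM in wild type and 418 and 394 FPKM in knockout. The stomach list's median was 0.16 (adjusted p = 0.279 by camera), 0.56 without WT_0 and -0.11 without WT_1. With the trend removed its median rose to 0.51, with 4 members higher and 1 lower, and the list did not pass. Between the wild type libraries, WT_0 minus WT_1, the median difference was 0.80 for the stomach list and -0.26 for the enterocyte list. Gkn3 stood at 5.12 and 5.47 FPKM in these libraries. As the whole cause, such unequal dissection would lower Hox genes of the trunk as far as the enterocyte list, whose upper bound was -0.69. But the 21 central and posterior Hox genes, which mesenchyme also expresses, had a median of -0.25 (bounds -0.43 and 0.19). Their median was from -0.51 to 0.05 on leaving out a library and 0.17 with the trend removed. The enterocyte median was from -1.19 to -1.01 on leaving out a library. A part of the fall from unequal dissection stays open beside the loss of Cdx2, a hypothesis found and weighed on the same libraries.

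A hypothesis on the short genes is that the groups' libraries differ technically. Of 120 miRNA and snoRNA genes tested, 37 were listed at 0 in both knockout libraries and 4 in both wild type libraries, and Mir6236 stood at 36775 and 35147 FPKM in wild type and 17.0 and 25.1 FPKM in knockout, while Mir682 went from 9548 and 12809 to 103458 and 91203 FPKM. Loss of the transcripts that hold them is argued against as the shared cause. Their 27 tested host genes, taken from 30 of the 37 small RNA genes, had a median log2 fold change of -0.14 (bounds -0.73 and 0.49). Of these hosts 10 were called lower and 8 higher. These bounds too treat genes as independent and leave out variation between libraries. A difference in library or alignment that acts on short genes may be the source, as fold changes of protein-coding genes also followed gene span with rho 0.37. But the rho of -0.34 between the knockout libraries was nearly as large, so the test, whose rule compared only rho, does not decide. The medians of the shortest and longest eighths were -0.48 and 0.14 between the groups and 0.12 and -0.07 between the knockout libraries. Each knockout library against each wild type library gave a rho from 0.32 to 0.40, and the wild type libraries against each other -0.01. Technical and genotype effects on these genes cannot be told apart, because the labels give no batch that holds both genotypes.

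Libraries of the same group differed from each other in several lists. Sox2 stood at 36.0 FPKM in WT_0 and 2.00 FPKM in WT_1, Irx3 at 8.25 and 0.267 and Irx5 at 7.28 and 0.0657, whereas Hoxb13, a gene of the hindgut, stood at 1.33 and 27.2 and Hoxa13 at 0.925 and 4.19. The median difference on the log2 scale, WT_0 minus WT_1, was 0.80 for the 17 stomach genes and -0.55 for the 21 central and posterior Hox genes. The same median was 1.20 for erythroid markers, 0.55 for anterior Hox genes, 0.52 for goblet and enteroendocrine genes, 0.42 for pancreas and liver genes, 0.41 for esophageal genes and 0.38 for mesenchyme markers. The knockout libraries differed as well, and KO_0 minus KO_1 was -0.62 for pancreas and liver genes, 0.55 for esophageal genes, 0.51 for endothelial markers, 0.71 for embryo sex genes and 0.25 for erythroid markers, but -0.09 for stomach genes and 0.12 for central and posterior Hox genes. No explanation of these differences was tested. The knockout libraries stood near WT_0 for Sox2, at 41.9 and 35.0 FPKM, so whether Sox2 differed between genotypes was left undecided by these libraries.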
